A study of Mus musculus with 2 samples.

How the data were processed

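Per the labels, FFPE sections of mouse brain were mounted on slides for the 10x Genomics Xenium assay, in which probes for chosen genes are decoded as single transcripts in place and assigned to segmented cells. The labels name the panel mBrain v1.1 and the instrument software xenium 4.0.1.0. The segmentation settings, the quality filter on decoded transcripts and the genome build behind the probes are not given in the sources used here. The authors deposited raw counts, 1 whole number per feature and segmented cell, with no normalisation. Each of the 2 slides came as 2 copies of its matrix, which differed in 0 entries, and 1 copy was used. Each matrix held 541 features, of which 247 were genes, 27 negative control probes, 41 negative control codewords, 225 unassigned codewords and 1 deprecated codeword. Gene symbols were taken from the feature lists in the deposited files. Each deposited matrix pools 8 brains and 4 areas per brain, and no deposited file gives cell positions or links a cell to a brain. The deposited coordinate tables give the corners of 32 named outlines per slide.

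A slide was therefore treated as 1 sample for every count of transcripts or cells. No test was run on these counts, and intervals are exact 95% intervals that cover counting error only. Cells with at least 10 transcripts were kept. Counts were summed per gene over the kept cells of a slide and divided by the slide's gene total and expressed as CPM, and the aged over adult ratio was given an interval from the exact conditional binomial distribution of the 2 counts. A gene was called higher or lower when it was at least 1.5-fold apart and held at least 500 counts on the 2 slides together. The named genes were the 12 with the highest and the 12 with the lowest ratio among genes with at least 1000 counts on each slide. Within a cell class they were the 5 highest and 5 lowest among genes with at least 500 counts of the class on each slide, and in a gene list the 2 highest and 2 lowest with at least 200 counts on each slide. These rules, the gene lists and the marker lists were set before the data were examined. Genes named outside them, such as the leading genes of clusters, were chosen after their values were seen. For equal weights, mean counts per cell were averaged over classes or clusters with the mean of both slides' shares, and the intervals come from counting error on the log scale.

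For clusters, 30000 cells per slide were drawn with a fixed seed, scaled to their totals, log-transformed, standardised per gene and reduced to 40 principal components with scikit-learn. A graph of 15 nearest neighbours was divided by the Leiden method at resolution 1 in scanpy with igraph, which gave 37 clusters. All kept cells were then assigned to a cluster by linear discriminant analysis on the same components. When trained on alternate cells of the subsample, this step placed 92.2% of the remaining cells in their own cluster. No doublet caller and no integration of the slides was run. A cluster was named for a class when at least 3 of the class's fixed markers were at least 1 log2 unit above the other cells and seen in at least 10% of its cells, when more of its top 10 genes were markers of that class than of any other, and when at least 1 was among its top 5 genes. The thresholds of this rule were set after the data were seen. It named 26 clusters in 11 classes, which are written as class-like cells, and the other clusters stayed unnamed. Microglia-like stands for the class microglia or macrophage, and leptomeningeal-like for leptomeningeal or fibroblast. Shares of cells were given exact Clopper-Pearson intervals. A cluster with over 90% of its cells from 1 slide could belong to that slide and not to a cell type, or be a cell type sampled on 1 slide only. Of this kind were 2 unnamed clusters, led by Cbln1, Nrep and Pkib and by Sntb1, Kcnmb2 and Angpt1. Clusters with the same leading genes were found at a higher and a lower resolution and with another random seed. The 90% cut was applied to all kept cells after assignment. In the subsample, a cluster led by Spp1 and Cd24a (32 cells) was 96.9% aged, and a cluster led by Pthlh and Tacr1 (55 cells) was 92.7% aged. After assignment they were 75.7% and 68.6% aged, so they were not counted among these 2.

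The 21 gene lists fixed beforehand were Microglial and immune activation, Astrocyte reactivity, Astrocyte identity, Activity-regulated genes, Myelinating oligodendrocytes, Oligodendrocyte precursors and newly formed oligodendrocytes, Immature neurons, Endothelium and blood-brain barrier, Mural cells, Leptomeninges and fibroblasts, Interneuron subtypes, Neuropeptides, Catecholamine and acetylcholine neurons, section-plane markers of the upper cortical layers, deep cortical layers, hippocampus CA, dentate gyrus, striatum, thalamus and midbrain, and Ependyma and ventricle. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size, drawn for each member from the 40 genes nearest in mean level. This percentile describes the 2 slides and is not a test across animals.

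Outline areas were taken as stated with the coordinates and differed by at most 1.9e-06% from areas computed from the corners. They were summed over the 4 areas of a brain, which gave 1 value per brain. Control and heat stress were compared within each cohort by an exact two-sided permutation test of the difference in means over the 70 splits, with Benjamini-Hochberg adjustment over the 2 cohorts and a threshold of adjusted p < 0.05.

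The steps for genes were tried on simulated Poisson counts with no spread between slides, brains or regions, which covers counting error alone. The changed profile was rescaled to its total, so true ratios moved away from the folds that were set. In the comparison over all cells, drawn with 247 genes, 50 of 50 genes set 2-fold apart reached 1.5-fold, as did 0 of 50 set 1.25-fold apart and 0 of 147 left alone. In endothelial-like cells, drawn with 247 genes, the same step called 37 of 37, 9 of 38 and 0 of 95 among the genes with enough counts. In microglia-like cells, drawn with 247 genes, it called 31 of 31, 0 of 25 and 0 of 91. Of 200 random lists, 7 fell outside the central 95% of their own random draws.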

Results

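Transcripts of 247 genes were counted in single cells of mouse brain sections on 2 Xenium slides, 1 from an adult cohort and 1 from an aged cohort. Each slide carried sections of 4 control brains and 4 brains of mice exposed to about 40 °C for 3 hours a day over 14 to 15 days, with 4 outlined areas per brain. The adult slide held 228762 segmented cells with 24680468 gene transcripts, and the aged slide held 211018 cells with 22011883. Cells with at least 10 transcripts made up 92.6% of the adult and 92.5% of the aged cells. In these cells the median was 64 transcripts on both slides, with 30 genes on the adult and 29 on the aged slide. After each cell with enough transcripts was thinned to 40, the median was 23 genes on both slides. The thinning left out 38.5% of the adult and 39.4% of the aged cells. The 27 negative control probes together held 1911 counts on the adult slide and 1736 on the aged slide, against 4071 and 3062 for Trp73, the gene with the fewest counts. Each slide is a single sample with no replicate slide, so ratios between slides carry intervals for counting error only.

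The comparison of heat stress with control asks what repeated heat exposure does to the adult and the aged brain. In the adult cohort the summed area of the 4 outlines of a brain was larger after heat stress. It was 13.1 ± 0.600 mm² (SD, n = 4) in heat-stressed brains and 12.1 ± 0.571 mm² (SD, n = 4) in control brains. The difference was 0.947 mm², or 7.82%, and 4 of 4 heat-stressed brains lay above the control mean. The exact permutation p was 0.0286 (two-sided, n = 4 per group), the smallest this design allows, and the adjusted p of 0.0571 did not pass the threshold. Adjusted over both cohorts, the adult cohort could pass only if the aged cohort also reached the smallest p. Not passing therefore does not by itself show that a difference is absent. In the aged cohort the area was 13.8 ± 0.352 mm² after heat stress and 13.4 ± 1.33 mm² in controls (SD, n = 4 each), a difference of 0.350 mm² or 2.60%, with 3 of 4 heat-stressed brains above the control mean and an exact permutation p of 0.857 (adjusted 0.857). This aged difference turned to -0.294 mm² without control brain 1. The heat effect differed between the cohorts by -0.597 mm² (exact permutation p = 0.513 over 4900 relabellings, n = 8 brains per cohort). None of the 4 areas taken alone passed the test in either cohort, with adjusted exact p of 0.686 or more. The smallest unadjusted exact permutation p was 0.143, in area 3 of adults. With this adjustment a single area could not have passed even at the smallest possible p. In adults the areas differed in direction, at -0.384 mm² in area 1, 0.172 in area 2, 0.655 in area 3 and 0.504 in area 4. Control brains lay at 1.27 to 8.49 mm and heat-stressed brains at 10.0 to 17.9 mm along the adult slide. On the aged slide control brains lay at 1.70 to 9.04 mm and heat-stressed brains at 11.1 to 18.5 mm. Condition and position were thus not separate on either slide. Single outlines covered 2.28 to 3.94 mm² on the adult slide and 2.54 to 4.18 mm² on the aged slide. The labels do not say what the 4 areas are or how outlines were drawn, so their sum cannot be read as brain size.

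**Figure D1:**
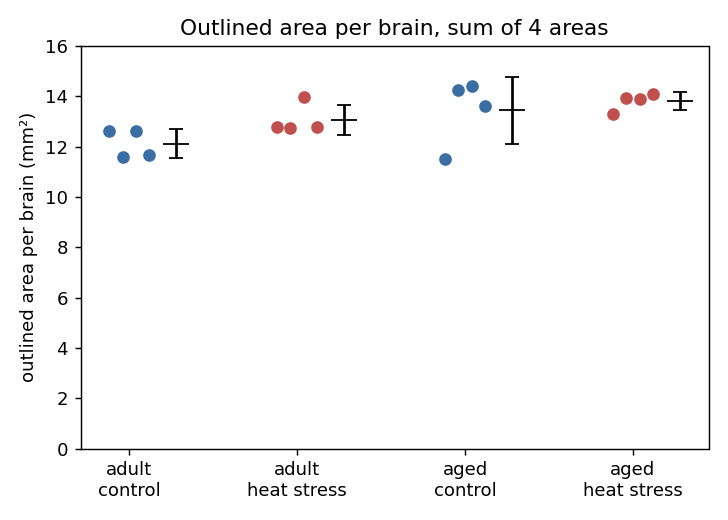
Outlined area per brain in mm², summed over 4 areas, for each cohort and condition. Points are brains, and black bars show the mean and SD of 4 brains. The adult heat-stressed brains lie between 12.7 and 14.0 mm² and the adult controls between 11.6 and 12.6 mm².

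Gene expression and cell classes after heat stress were not analysed here. The cells of control and heat-stressed brains share 1 matrix per slide, and no deposited file says which cell came from which brain. Every comparison of genes and cells below is therefore between the aged and the adult slide, each with both conditions pooled.

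Over all cells, 6 of 247 genes were at least 1.5-fold higher on the aged slide and 5 were at least 1.5-fold lower. The higher genes were Chat, which makes acetylcholine, at 2.31-fold (95% interval 2.25 to 2.38), Prph, a neuronal intermediate filament, at 1.86-fold, Chodl at 1.70-fold, Sncg, a synuclein, at 1.54-fold, Pthlh at 1.52-fold and the opioid precursor Pdyn at 1.51-fold. The lower genes were Cbln1, a secreted organiser of synapses, at 3.10-fold lower, Fibcd1 at 1.91-fold lower, Pde11a, a cyclic nucleotide phosphodiesterase, at 1.80-fold lower, Syt17 at 1.65-fold lower and Dcn, the matrix proteoglycan decorin, at 1.53-fold lower. Chat (ENSMUSG00000021919) was at 329 CPM on the adult slide and 762 on the aged slide. Cbln1 (ENSMUSG00000031654) was at 3446 and 1111 CPM. Other genes among the 12 highest were the microglial receptors Cd300c2 at 1.42-fold and Trem2 at 1.33-fold, the leptomeningeal genes Slc13a4 at 1.42-fold, Fmod at 1.35-fold and Aldh1a2 at 1.32-fold, and Nts, the neurotensin precursor, at 1.39-fold. The cilium gene Spag16 was 1.48-fold lower, and Nwd2, Ndst3, Bhlhe22, Nrep, Rspo2 and Gm19410 were 1.37-fold to 1.46-fold lower.

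Some of these genes came mainly from 1 cell group and others from several. One unnamed cluster held 83.5% of the adult and 89.3% of the aged Chat counts, 33.5% and 58.2% of the Prph counts, 48.3% and 66.5% of the Chodl counts and 27.3% and 39.4% of the Sncg counts. This cluster made up 0.336% of adult and 0.623% of aged cells. Another unnamed cluster, found almost only on the adult slide, held 54.6% of the adult Cbln1 counts. Without the 2 clusters found almost only on 1 slide, Cbln1 had a ratio of 0.712 and did not pass 1.5-fold, and 4 genes were higher and 4 lower. Excitatory neuron-like cells held 41.3% of the adult Dcn counts, while leptomeningeal-like cells held 68.8% of the aged ones. With equal class weights on both slides, 0 genes stayed at least 1.5-fold higher and 5 lower, and Spag16 turned to a log2 ratio of 0.24. With equal cluster weights, which also level the clusters within a class, 0 of the 6 higher genes and 2 of the 5 lower genes, Cbln1 and Pde11a, stayed past 1.5-fold. Of the 11 genes called, 54.5% were higher when scaled to the gene total, 40.0% of 10 with median-of-ratios scaling and 30.0% of 10 as mean counts per cell.

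**Figure D2:**
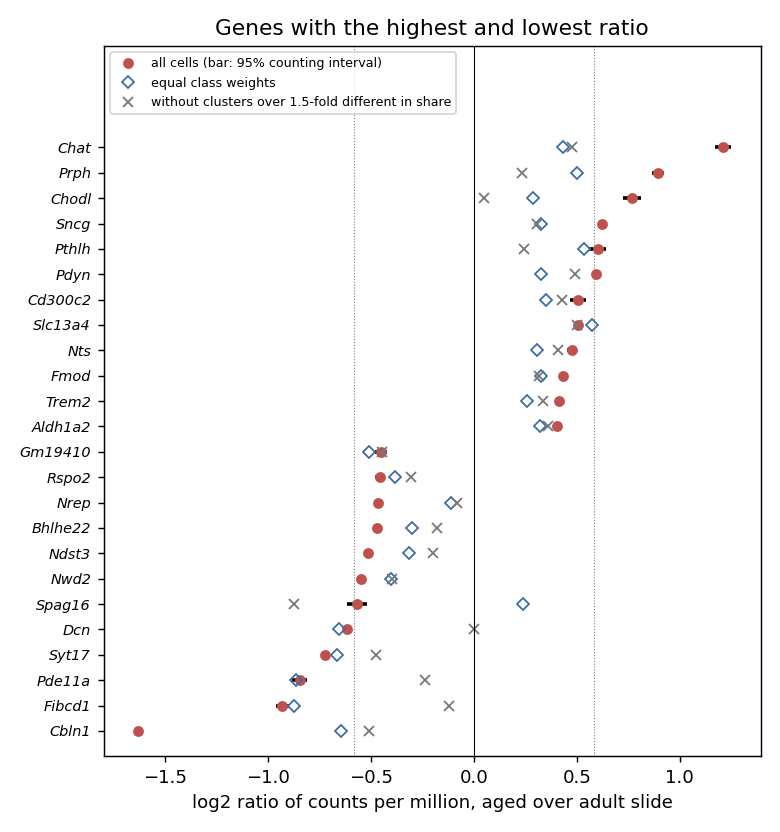
Log2 ratio of CPM, aged over adult slide, for the 12 genes with the highest and the 12 with the lowest ratio. Filled circles are all cells, with bars for the 95% counting interval, open diamonds are values with equal class weights, crosses leave out 12 clusters over 1.5-fold different in share, and dotted lines mark 1.5-fold. Chat is highest at 1.21 and Cbln1 lowest at -1.63, and Spag16 lies below 0 over all cells and above 0 with equal class weights.

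Genes of microglial and immune activation lay mostly higher on the aged slide. Of 12 members 11 had a ratio above 1, none passed 1.5-fold, and the median log2 ratio was 0.26, at the 99.2 percentile of random lists. Within microglia-like cells, whose share was 1.20-fold higher on the aged slide, 7 of 11 members with enough counts were above 1 and the median was 0.02, at percentile 51.2. Cd300c2 and Trem2 were highest, while Cd44, an adhesion receptor, was at 0.940 and Trbc2 at 1.01. Leptomeninges and fibroblasts had 9 of 12 members above 1 and a median of 0.20 at percentile 99.2, with Slc13a4 and Fmod highest and Dcn lowest. Within leptomeningeal-like cells, whose share was 1.14-fold higher, 7 of 12 members were above 1 and the median was 0.02, at percentile 65.2. Catecholamine and acetylcholine neurons had 4 of 4 members above 1 and a median of 0.57 at percentile 99.8, led by Chat and Prph, with the dopamine genes Slc6a3 at 1.19 and Th at 1.06. The striatum markers had 5 of 5 members above 1 and a median of 0.21 at percentile 97.8, from Pdyn at 1.51 and the enkephalin precursor Penk at 1.30 down to Meis2 at 1.07. With equal class weights only the leptomeningeal list stayed outside the central 95% of random lists, and the medians of the acetylcholine and striatum lists went to 0.06 and 0.04, and to 0.03 and -0.04 with equal cluster weights.

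The other 17 lists lay within the central 95% of random lists, though the myelinating list and the deep cortical layers moved just outside, to percentiles 97.6 and 97.9, without the 2 clusters found almost only on 1 slide. With equal cluster weights the midbrain list moved outside as well, to percentile 1.495 with a median of -0.35. Myelinating oligodendrocytes had 5 of 5 members above 1 and a median of 0.14, with Gjc3, a gap junction protein, at 1.26 and Sox10 at 1.23. Endothelium and blood-brain barrier had 15 of 16 above 1 and a median of 0.15, with Ly6a at 1.28 and the carbonic anhydrase Car4 at 0.820. Astrocyte reactivity had a median of -0.05, with the astrocyte filament gene Gfap at 1.23 and Igfbp5 at 0.879. Astrocyte identity had a median of 0.07, mural cells 0.07 with Carmn at 1.20 and Nr2f2 at 0.809, and oligodendrocyte precursors and newly formed oligodendrocytes 0.03. Activity-regulated genes had a median of -0.01, with the immediate early genes Arc at 0.741 and Fos at 0.766 lowest and Penk at 1.30 highest. Immature neurons had 4 of 5 members below 1 and a median of -0.19, with Nrep at 0.724 and the granule neuron gene Prox1 at 1.19. Clusters found almost only on the adult slide held 27.99% of the adult Nrep counts, and without them Nrep was at 0.979 and the list median at -0.06. Interneuron subtypes had a median of 0.08, with Chodl and Pthlh past 1.5-fold and Vip at 0.881, and neuropeptides a median of -0.02 with Pdyn highest.

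Markers of brain regions that depend on the plane of a section went both ways. The hippocampus CA markers had 5 of 6 members below 1 and a median of -0.12, with Fibcd1 past 1.5-fold and Cpne6 at 0.798. The thalamus markers had 6 of 7 below 1 and a median of -0.18, with Necab1 at 0.804. The deep cortical layers had 7 of 9 above 1 and a median of 0.15, though Fezf2, a gene of deep-layer projection neurons, was at 0.775. The upper cortical layers had a median of 0.04 with Calb1 at 0.823, and the dentate gyrus 0.05 with Prox1 at 1.19. Ependyma and ventricle had 3 of 3 below 1 and a median of -0.25, and midbrain 3 of 3 above 1 and a median of 0.16. These last medians turned to 0.24 and -0.32 with equal class weights. The hippocampus CA median turned to 0.08 with equal cluster weights, with 4 of 6 members above 1.

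Among 11 named cell classes, only ependymal or choroid plexus-like cells differed at least 1.5-fold in their share of cells, at 1.27% of adult cells (95% interval 1.22 to 1.32) and 0.635% of aged cells (0.601 to 0.672). The files do not say whether the sections of both slides came from the same level along the brain, on which the share of a class bound to a region depends. Striatal projection neuron-like cells made up 5.72% on the adult and 7.82% on the aged slide, oligodendrocyte-like cells 16.5% and 19.8%, microglia-like cells 3.31% and 3.96%, and leptomeningeal-like cells 2.84% and 3.24%. Excitatory neuron-like cells made up 20.3% on the adult and 18.5% on the aged slide. Inhibitory neuron-like cells stood at 10.1% and 9.88%, astrocyte-like cells at 9.45% and 9.79%, and oligodendrocyte precursor-like cells at 2.44% and 2.47%. Endothelial-like cells stood at 7.47% and 7.88%, and mural-like cells at 3.36% and 3.53%. Unnamed clusters held 17.2% of adult and 12.6% of aged cells. Of the 37 clusters, named or not, 12 differed over 1.5-fold in share and held 13.5% of adult and 4.15% of aged cells. Among them, unnamed clusters led by Cbln1 and Nrep stood at 4.33% and 0.0123%, and by Sntb1 and Kcnmb2 at 1.54% and 0.0318%. Others went the other way, such as an unnamed cluster led by Spp1 and Cd24a at 0.0775% and 0.261%. In the clustered subsample this cluster was 96.9% aged, so its adult share rests largely on the assignment of the other cells. The larger of the ependymal clusters was mixed, since 23.8% of its adult and 10.4% of its aged cells had no Spag16 or Trp73 and at least 3 counts of immune genes.

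**Figure D3:**
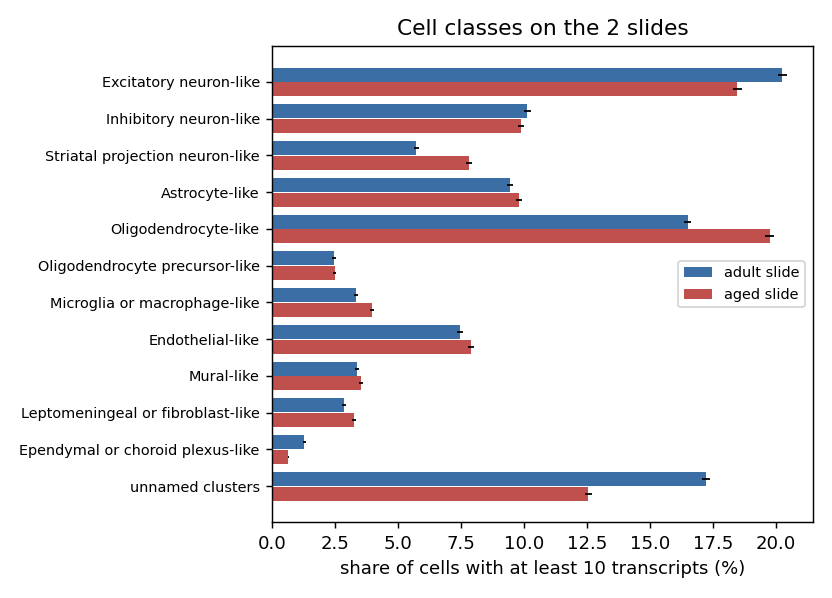
Share of cells with at least 10 transcripts in each class, in percent, on the adult and aged slide. Bars start at 0 and black lines are exact 95% counting intervals. Ependymal or choroid plexus-like cells have 1.27% on the adult and 0.635% on the aged slide.

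Within excitatory neuron-like cells, 4 of 235 genes with enough counts were at least 1.5-fold higher on the aged slide and 28 were lower. Dcn went from 47960 counts to 922 (39.4-fold lower, 36.9 to 42.1) and Pde11a from 8430 to 684 (9.33-fold lower). Arhgap6 was 3.77-fold lower, Cd44 2.86-fold lower and the semaphorin Sema3d 2.22-fold lower. Pvalb, the calcium buffer parvalbumin, was 1.88-fold higher, and Ndst4, Opn3 and Arhgap25 were each 1.53-fold higher. The 8 clusters of this class were mixed differently on the slides, since a cluster led by Rprm and Bhlhe22 made up 2.41% of adult and 0.624% of aged cells, a cluster led by Fibcd1 1.54% and 0.813%, and a cluster led by Bhlhe22 and Rasl10a 3.21% and 4.22%. In the excitatory cluster that holds most Fibcd1, the mean Dcn count was 7.92 per adult cell and 0.00630 per aged cell. Dcn in leptomeningeal-like cells, outside the rule for named genes, had a ratio of 0.913, and in mural-like cells 0.971.

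In inhibitory neuron-like cells 6 genes were higher and 4 lower on the aged slide. Mecom, a transcription factor gene, was 2.72-fold higher, Lamp5, a marker of an interneuron group, 1.60-fold, Pthlh 1.56-fold and Sncg 1.56-fold. Prdm8 was 2.09-fold lower, Sla 2.03-fold, Bhlhe22 1.93-fold and Calb1, the calcium buffer calbindin, 1.57-fold lower. The cluster mix differed here too, with a cluster led by Pvalb and Kcnmb2 at 0.619% of adult and 0.350% of aged cells and a cluster led by Pthlh and Tacr1 at 0.0841% and 0.199%. The cluster led by Pthlh and Tacr1 was 92.7% aged in the clustered subsample. In striatal projection neuron-like cells 16 genes were higher and 13 lower, with Rasgrf2 at 3.70-fold, Rprm at 3.39-fold, Nrp2 at 3.21-fold and Cux2 at 2.12-fold higher. Fos was 2.08-fold lower there, Arc 1.77-fold, Adamts2 1.74-fold and the cadherin Cdh13 1.72-fold lower. At a higher cluster resolution 18 genes passed in the striatal class in place of 29, Rasgrf2 was 1.94-fold and Rprm 2.25-fold higher, and the ratios of Nts and Vwc2l turned from 1.82 to 0.848 and from 0.430 to 1.29. Markers of other neurons moved with this change, since Rasgrf2 and Cux2 are on the excitatory neuron list, 6 of 6 upper cortical layer markers had a ratio above 1 in this class, and the hippocampus CA markers had a median of 0.46 at percentile 99.5. At the higher resolution a cluster led by Wfs1, Pdyn and Foxp2 was unnamed, and with another random seed such a cluster was named excitatory.

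In astrocyte-like cells 1 gene was higher and 8 were lower, with the neuronal genes Calb1 at 2.21-fold, Bhlhe22 at 1.75-fold and Calb2 at 1.71-fold lower and Fos at 1.49-fold higher. In oligodendrocyte-like cells Eya4, a transcriptional coactivator, was 1.66-fold higher and Sema3d 2.19-fold lower, among 2 higher and 3 lower genes. Oligodendrocyte precursor-like cells had 1 gene higher and 4 lower, of which Cpne6 at 1.66-fold, Slc17a7, the vesicular glutamate transporter, at 1.64-fold and Bhlhe22 at 1.62-fold lower mark excitatory neurons. Cpne6 was also 1.55-fold lower in microglia-like cells, where 3 genes were higher and 4 lower. Spp1, the secreted protein osteopontin, was 2.88-fold higher in microglia-like cells (2.64 to 3.14), at 675 and 2216 counts, and 1.76-fold higher at a lower cluster resolution. The microglia-like cells with at least 5 Spp1 counts were 28 of 7002 on the adult slide and 96 of 7729 on the aged slide, and they held 47.4% and 79.0% of these counts. The class covers microglia and macrophages, which were not separated.

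Fos, an immediate early gene induced by cell stimulation, differed in direction between cell classes. In endothelial-like cells, where 1 gene was higher and 3 lower, it was 6.48-fold higher on the aged slide (5.72 to 7.38), at 281 and 1841 counts, and was found in 1.35% of 15809 adult and 5.87% of 15371 aged cells (median 35 and 36 transcripts). Oligodendrocyte-like cells, with a median of 27 transcripts, had Fos in 0.976% and 0.843% of cells. It was 2.66-fold higher in mural-like cells, where 2 genes were higher and 1 lower. The 5 lowest named genes in mural-like cells included the leptomeningeal markers Col6a1 at 0.714 and Col1a1 at 0.743. The endothelial genes Mecom and Pecam1 were among the top genes of a cluster of this class, and at a higher cluster resolution an endothelial cluster led by Acta2 and Mecom and with Fos among its top genes was found, and Fos was then 2.05-fold higher in mural-like and 4.68-fold higher in endothelial-like cells. Fos was 1.59-fold higher in leptomeningeal-like cells, where 2 were higher and 3 lower. In excitatory neuron-like cells Fos had a ratio of 0.747 and in inhibitory neuron-like cells 0.713, and Arc had 0.779 and 0.742. Arc, also induced by activity, had a ratio of 0.721 in endothelial-like cells. Fos in endothelial-like and mural-like cells had under 500 counts on the adult slide and was picked after its values were seen, as were the neuronal ratios. Leptomeningeal-like cells also had Rspo2, a secreted Wnt pathway activator, at 2.06-fold higher, and Gjc3 at 1.56-fold and Penk at 1.55-fold lower. Ependymal or choroid plexus-like cells had 2 genes higher and 13 lower, with Rmst at 1.51-fold higher and Cd24a at 1.68-fold and Kctd12 at 1.65-fold lower. Immune genes moved with this change, since 5 of 6 members of the microglial and immune list with enough counts, among them Cd53, Cd68, Ikzf1 and Laptm5, which were picked after their values were seen, were at least 1.5-fold lower in this class, and the list median was -1.53. In that class 48 genes passed as mean counts per cell and 2 at a lower cluster resolution, and Plekha2, Aqp4 and Dner turned direction with mean counts per cell.

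**Figure D4:**
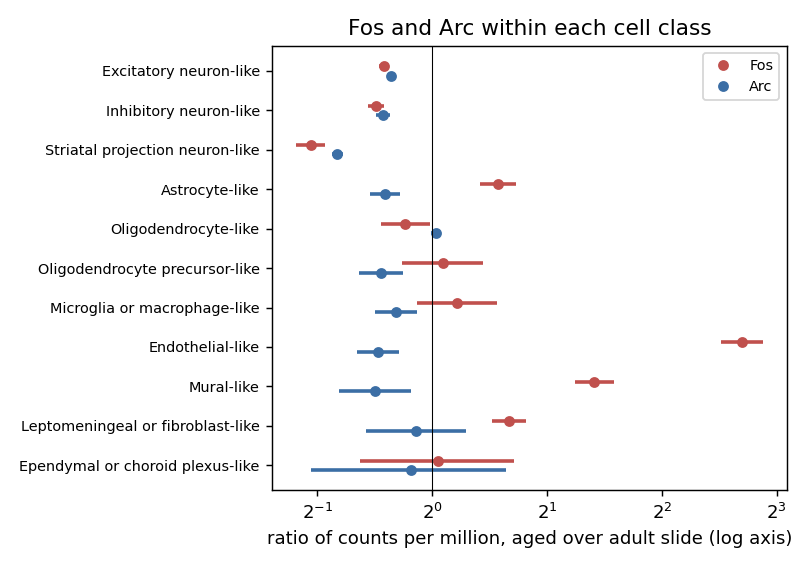
Ratio of Fos and Arc CPM within each cell class, aged over adult slide, on a log axis. Points are ratios and lines are exact 95% counting intervals for 1 slide per age. Fos is at 6.48 in endothelial-like cells, where Arc is at 0.721, and at 0.480 in striatal projection neuron-like cells.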

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

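All tests of explanations in this part were chosen after the results were seen. In the adult heat stress group, 1 brain had an outlined area of 14.0 mm² (13.9622), while the other 3 lay close together from 12.7 mm². Its gap to the nearest brain was 0.945 of the group's range. Of 4 groups of brains examined this way 1 stood out, and chance does so in about 5% of such groups. Without this brain the adult difference between heat stress and control was 0.648 mm².

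Codewords that belong to no panel gene also held signal. A codeword listed as deprecated held 57108 counts on the adult slide and 70625 on the aged slide, more than 119 and 141 of the 247 genes, while the highest negative control probe held 1351 and 1160. It was 1.39-fold higher on the aged slide relative to gene counts (1.37 to 1.40), and was found mainly in microglia-like cells, at 239 and 364 counts per 100 cells, in leptomeningeal-like cells, at 263 and 339, and in ependymal or choroid plexus-like cells, at 321 and 103. In excitatory neuron-like cells it stood at 3.25 and 4.67 per 100 cells. The files do not name its gene, and no explanation was tested. Of 225 unassigned codewords, 28 on the adult slide and 19 on the aged slide held more counts than every negative control codeword, of which the highest held 48 and 73.

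The 11 genes at least 1.5-fold apart over all cells could reflect different shares of cell clusters on the slides. With equal cluster weights 0 of the 6 higher genes stayed 1.5-fold higher. Pdyn, Pthlh and Sncg stood near that line beforehand, at 1.51-fold to 1.54-fold, so crossing it says little for them. Chat went from 2.31-fold (2.25 to 2.38) to 1.32-fold (1.29 to 1.36), Chodl from 1.70-fold to 1.18-fold and Prph from 1.86-fold to 1.40-fold. Pdyn went to 1.20-fold and Sncg to 1.22-fold, while Pthlh went only from 1.52-fold to 1.42-fold (1.38 to 1.46). Such shares fit as part of these differences, but as little of that of Pthlh, and each gene kept a difference. For the 5 lower genes it cannot be told apart, since 2 stayed 1.5-fold lower with equal cluster weights, Pde11a at 1.57-fold (1.53 to 1.62) and Cbln1 at 1.62-fold (1.498 to 1.76), which rests on a cluster with 24 aged cells, while Fibcd1 went from 1.91-fold to 1.35-fold lower, Syt17 from 1.65-fold to 1.43-fold and Dcn from 1.53-fold to 1.44-fold. A few genes taking most of the counts is argued against, since the 10 most counted genes held 21.1% of adult and 21.0% of aged counts, a factor of 1.00 on all other genes. Age of the animals cannot be told apart from the slide for these 11 genes, with 1 slide per age. A different level of the sections along the brain stays open and untested for them and for the shares of cell classes. The files give neither the level nor the place of a cell. A cluster led by Cbln1 and Nrep made up 4.33% of adult and 0.0123% of aged cells, so the slides hardly shared it.

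Fos was higher in endothelial-like cells on the aged slide, and Fos counts from neighbouring neurons could have produced this. Against that, Arc, another neuronal activity gene, had a ratio of 0.721 in the same cells (0.634 to 0.819). A brighter Fos signal over the whole aged slide is argued against by the ratio of 0.747 in excitatory neuron-like cells (0.727 to 0.767). Handling or staining of 1 slide that acts on vessel cells cannot be told apart from age for the 6.48-fold difference, since each age is a single slide processed as a whole. Heat stress is also open, because control and heat-stressed brains are pooled in each matrix.

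Spp1 was higher in microglia-like cells on the aged slide, and counts from neighbouring leptomeningeal cells are a candidate source. The leptomeningeal gene Fmod was higher in the cells of at least 5 Spp1 counts than in the other microglia-like cells, at 0.750 against 0.0244 per adult cell and 0.281 against 0.0333 per aged cell, so some counts of this kind could be present. On the aged slide leptomeningeal-like cells held 6.52 counts of Fmod, Slc13a4, Dcn and Igf2 per Spp1 count, so that, if all counts of these 4 genes in microglia-like cells were theirs, they would bring 22.5% of the Spp1 counts (21.3 to 23.7), against the 65.3% in excess of the adult level, which argues against them as the whole cause. Spp1 from other neighbouring cells was not tested. Age of the animals cannot be told apart from the slide for the 2.88-fold difference, with 1 slide per age.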

How the results depend on the processing

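The alternatives without some clusters, with equal cluster weights and those for Fos and Spp1 within classes were chosen after the data were seen, and all others before the data were examined. Over all cells, 6 genes were at least 1.5-fold higher and 5 lower, and both counts were the same with all cells, with cells of at least 40 transcripts, with no minimum count, with at least 5000 counts and without the 10 most counted genes in the total. As mean counts per cell 3 were higher, at the lower fold threshold 23 were higher and 21 lower, and at 2-fold 1 was higher and 1 lower, the last 2 settings by their own construction. With equal class weights 0 were higher and Spag16 had a log2 ratio of 0.24 in place of -0.57, and 1 list lay outside the central 95% of random lists in place of 4. With equal cluster weights 1 gene was higher, Ndst4, which was not among the 6, and 2 were lower, Spag16 was at 0.20, 2 lists lay outside, and the striatum list had a median of -0.0367 in place of 0.211. Without the clusters over 1.5-fold different in share 0 genes were higher and 1 lower, Spag16, which was not among the 5, Dcn had a log2 ratio of 0.0028 in place of -0.62, and 2 lists lay outside. Leaving out clusters also removes differences within them. Without the clusters found almost only on 1 slide 4 genes were higher and 4 lower, and 6 lists lay outside. Apart from the weights and the clusters left out, the cause was not tested. Of 24 named genes, 23 kept their direction in all 6 alternatives fixed beforehand that give a value per gene, Spag16 being the exception. Of the 21 lists, 9 kept the sign of their median in every alternative.

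The genes at least 1.5-fold apart within classes, 124 summed over classes, ranged from 116 to 169. In every alternative only ependymal or choroid plexus-like cells were 1.5-fold different in share, with a ratio of 0.471 to 0.596. Endothelial-like, mural-like, astrocyte-like, leptomeningeal-like and oligodendrocyte precursor-like shares were above 1 in some alternatives and below in others. The difference in outlined area ranged from 0.648 to 1.11 mm² in adults without 1 brain each, and from -0.294 to 0.671 mm² in aged brains. In adults the exact permutation p was then 0.0571. This is the smallest possible with 1 brain left out, so its rise does not show a weaker difference. The aged value of -0.294 mm² came without control replicate 1, and the difference in medians was -0.0342 mm² (exact permutation p = 1); the cause was not tested. With the replicate number as a block the exact p was 0.125 in adults, the smallest it allows, and 0.750 in aged brains. Same-numbered brains had areas that correlated over 0.1 in 3 of 4 adult and 2 of 4 aged pairs and deviated the same way in 3 of 4 and 4 of 4, and the labels give the number no meaning, so the brains were not taken as pairs. Heat stress against control by gene, its difference between ages and its test within classes were not run, with all their alternatives, because no file links cells to brains. Depth limits genes within the smaller classes, of which 96 of 247 had enough counts in ependymal or choroid plexus-like cells.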

Other observations

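All values in this part were chosen after the results were seen, and no test of an explanation was run on them. The microglia-like cells with at least 5 Spp1 counts were 28 on the adult and 96 on the aged slide. They held more transcripts than the other microglia-like cells, at a mean of 101 against 43.7 on the aged slide and 98.5 against 42.7 on the adult slide. On the aged slide they had a mean of 9.82 counts of the lysosomal gene Cd68 per cell against 2.24 in the others, and 9.85 against 3.88 of Trem2, a receptor for lipids. Siglech, a gene of resting microglia, was at 2.47 against 4.54. The adult slide showed the same order, with Cd68 at 6.96 against 1.86, Trem2 at 7.71 against 3.46 and Siglech at 2.96 against 4.76. These are counts per cell, not scaled to the larger transcript totals of the cells picked for Spp1. Trem2 rose by no more than these totals on the adult slide and by little more on the aged slide, so it does not set these cells apart. Gfap, a gene of astrocytes, was also higher in these cells, at 2.58 against 0.370 on the aged slide and 0.750 against 0.291 on the adult slide, as was the leptomeningeal gene Fmod, at 0.281 against 0.0333 and 0.750 against 0.0244.

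The excitatory cluster that holds most Fibcd1 had 3269 adult and 1587 aged cells. Beside Dcn, its mean counts per cell went from 1.57 to 0.154 for Pde11a, from 1.55 to 0.223 for Rspo2 and from 2.253 to 0.4997 for Syt17, while Fibcd1 went from 6.01 to 4.13. Another excitatory cluster, with 5106 adult and 1217 aged cells, had Dcn at 3.98 and 0.343 per cell and Syt17 at 1.71 and 1.81.

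The outlined area per brain was 12.6 ± 0.742 mm² on the adult slide and 13.6 ± 0.922 mm² on the aged slide (SD, n = 8 each), a difference of 1.03 mm² (exact permutation p = 0.0283, two-sided, unadjusted). Each slide is 1 age, so slide and age are the same split here. The outlines of a slide covered 101 mm² on the adult and 109 mm² on the aged slide. All segmented cells of a slide over this area gave 2271 and 1936 cells per outlined mm². Cell positions are not given, so the cells inside the outlines are unknown and these values are not cell densities.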
